A study of Candida albicans and Saccharomyces cerevisiae with 2 samples.

How the data were processed

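The deposited data were 2 count tables, 1 per library, with genes in rows and 2000 barcodes in columns. Per the labels' protocols, yeast cells were encapsulated 1 by 1 in agarose microgels, cultured in synthetic medium for 18 hours, lysed in droplets with enzyme and detergent, and processed by the Drop-seq procedure, which captures polyadenylated RNA. Per the submitters' processing notes, bcl2fastq and Bowtie were used. Their versions and roles, the genome build, the annotation and the counting program are not given in the sources used here. The values the authors deposited are whole-number counts per gene and barcode, with no normalization. Whether molecular identifiers were collapsed into these counts is not given in the sources used here, so they are called counts, and amplified copies of 1 molecule could make intervals too narrow. Each table has exactly 2000 barcodes, so that number is not a number of colonies. How the authors chose the barcodes is not given, and no doublet caller was run, since 2 colonies behind 1 barcode have no fixed signature here.

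The C. albicans table had 12225 rows, with separate rows for the A and B alleles of most loci. Of 6097 B rows, 6015 were matched by locus to RefSeq genes of assembly ASM18296v3, used for names and gene order only, and rows of 1 locus were summed to give 6261 genes. Of 2904 rows with a gene name, 2867 had that name in the RefSeq table. Among 1570 allele pairs with at least 200 counts, the median share of the A row was 50.2%, and 50% lay inside the exact interval in 1207 pairs. The rows of a locus were not independent. The variance of their scaled difference over barcodes had a median of 0.797 over 1566 pairs outside rRNA, against 0.990 when the summed counts were split at random. In C. albicans, intervals are therefore too narrow, Fano factors of summed rows too high, and the 2 random splits of a barcode not fully separate, while simulated barcodes do not share counts in this way. This was tested after seeing the data. The S. cerevisiae table had 6769 rows. Rows of near-identical genes, such as CUP1-1 and CUP1-2, are uncertain because the counting could split shared reads. Strand use in the counting is not given.

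Barcodes with at least 200 counts were used, which left out 2 C. albicans barcodes and 1 S. cerevisiae barcode. Levels are CPM, counts scaled to the total of the library or cluster, rRNA included. Shares carry exact Clopper-Pearson 95% intervals and ratios exact conditional intervals. List members with at least 20 held-out counts were compared after adding 0.5 counts. A ratio against 0 counts is a lower bound against a floor of 3 counts. For detection and variation, each barcode was thinned without replacement to the 25th percentile of counts (1004 in C. albicans and 1569 in S. cerevisiae), which left out 496 and 500 shallower barcodes. Genes with a mean of at least 0.05 counts per thinned barcode were given a Fano factor. It was set against a level that about 1 in 1000 such genes exceeded in simulated barcodes with 1 common profile. Co-variation was the mean pairwise Pearson correlation of the thinned counts of the members of a list. It is given as a percentile among 10000 random lists whose members were drawn from the 20 genes nearest in mean expression. These percentiles describe 1 library and are not p-values. Gene lists, 14 for C. albicans and 24 for S. cerevisiae, were fixed before the data were examined.

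Clusters were made on 1 random split of each barcode's counts with the Leiden method at resolution 0.5, with 15 neighbours, 20 principal components and the 1000 most variable genes of log counts per 10000. Genes were described in the other split. For list levels, the list's own genes were left out of the clustering, an alternative chosen after seeing the data. Each cluster so made took the number of the main cluster most of its barcodes lay in, and clusters with 1 number were merged. A list is described by its members at least 2-fold higher or lower and by the percentile of its median log2 ratio among 10000 random lists. Genes that define a cluster are given as definitions. Clusters are named by number because no marker list fixed beforehand gives their types.

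The genes named were, per library, the 15 with the highest counts outside ribosomal proteins, the 15 with the highest Fano factor, each white, opaque, aromatic, deleted-marker, a-specific and alpha-specific gene, up to 4 of the highest genes of every other list, and the 5 leading genes of each cluster with at least 20 held-out counts. This rule and the main settings were fixed before the data were examined. Alternatives were other minimums on counts per barcode, leaving out the 5% of barcodes with most counts, thinning to the median, means over barcodes, no gene minimum, scaled counts, rank correlation, depth without ribosomal protein genes, other resolutions and 3 equal groups of barcodes by ARO4. Chosen after seeing the data were rRNA left out, allele rows kept apart, clustering after thinning, list levels without the member with most counts, and ARO4 ratios within clusters.

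The procedure was tested on simulated counts drawn from each library's own profile and depths, with 200 genes given 2-fold or 4-fold differences between 2 states. In the C. albicans simulation 22 of 81 tested genes with a 4-fold difference and 5 of 87 with a 2-fold difference exceeded the simulated variation level, and 5 of 1607 unchanged genes did. In S. cerevisiae these were 32 of 83, 13 of 87 and 1 of 2136, so both 2-fold and 4-fold differences are mostly missed at this depth. Simulated barcodes with 1 common profile still gave 2 clusters in both libraries, with an adjusted Rand index between splits of 0.546 and 0.549, and agreement between splits is read against those values. Barcodes simulated with 2 states gave 2 clusters in C. albicans and 4 in S. cerevisiae. Their agreement with the true states was 0.916 and 0.726, and between splits 0.832 and 0.795. The number of clusters is therefore not a number of states. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.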

Results

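Transcript counts were collected from colonies of the yeasts Candida albicans and Saccharomyces cerevisiae that had each grown from 1 cell inside an agarose microgel for 18 hours. Colonies were lysed in droplets and their polyadenylated RNA was captured on barcoded beads by the Drop-seq procedure, so that 1 barcode is taken here as 1 colony. There were 2 libraries, 1 per group: C. albicans strain RZY122, labelled as opaque, and S. cerevisiae strain BY4741, a standard laboratory strain, carrying an ARO4 library. The C. albicans library held 3335289 counts and the S. cerevisiae library held 6793535, each over 2000 barcodes. With 1 library per group there was no replicate, barcodes are not replicates, and no test between groups was possible. Intervals are exact (Clopper-Pearson) 95% binomial or conditional intervals and cover counting error only, and those for C. albicans are too narrow because the allele rows share counts. CPM stands for counts scaled to a common total per library or cluster.

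A C. albicans barcode held a median of 1236 counts and 396 genes, over 1998 barcodes with at least 200 counts. Its range was 356 to 17600 counts. An S. cerevisiae barcode held a median of 2282 counts and 687 genes over 1999 barcodes, with a range of 867 to 31560 counts. Ribosomal RNA rows took 53.9% of the C. albicans counts, mainly RDN25 with 1337271 counts and RDN18 with 448981 counts. The rRNA share of a C. albicans barcode had quartiles of 36.2% and 65.7%. In S. cerevisiae the rRNA rows counted as such were the mitochondrial ones, and they took 0.922% of counts. Without rRNA the median C. albicans barcode held 596.5 counts.

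The first question, from the label, was whether the C. albicans colonies carried the transcripts of the opaque cell type, a switched state of this yeast with its own set of expressed genes. The library labelled opaque held few transcripts of opaque markers and many of white markers. The 11 opaque markers together took 0.0164% of counts (0.0150% to 0.0178%) and the 5 white markers 0.527% (0.519% to 0.535%), of which ADH1, an alcohol dehydrogenase, gave 14586 of 17576 counts. WH11, a gene of white cells, had 2290 counts, or 687 CPM (659 to 715). EFG1, a regulator of the white state, had 424 counts. Of the opaque markers, OP4 had 4 counts, SAP1 had 1 and SAP3, like SAP1 a secreted protease gene, had 6. WOR1, the central regulator of the opaque state, had 31 counts, or 9.29 CPM (6.32 to 13.2). CDR3 had 31 counts, WOR3 had 17, STE2 had 6 and PBR1 had 1. The regulators WOR4, CZF1 and WOR2 had 195, 138 and 116 counts and made up most of the opaque list. The other white markers, NRG1 and ECM331, had 254 and 22 counts. There was no white library to set these levels against.

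**Figure D1:**
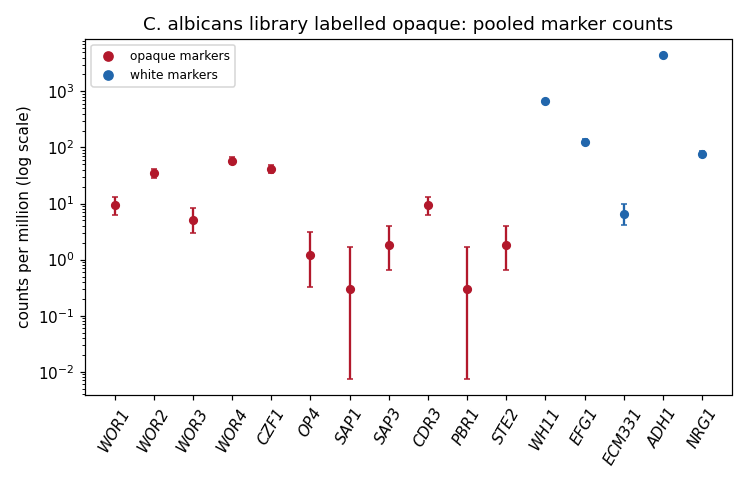
Pooled CPM (log scale) of the 11 opaque markers (red) and the 5 white markers (blue) in the C. albicans library labelled opaque, with exact 95% intervals for counting error. OP4 lies at 1.20 CPM and WH11 at 687.

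The share of barcodes with a marker was compared at 1 depth, in 1502 barcodes thinned to 1004 counts (496 shallower barcodes were left out). WH11 was seen in 40.1% of thinned barcodes (37.7% to 42.7%) and in 46.5% of all barcodes. EFG1 was seen in 11.4% of thinned barcodes and ADH1 in 90.5%. WOR1 was seen in 0.999% (0.560% to 1.64%), OP4 in 0.133%, and SAP1 and PBR1 in none. A count of 0 here limits barcodes with a count to 0.245%, not colonies that express the gene. Among the opaque list WOR4 was seen most often, in 5.53%. Filament markers were also rare: ALS3, a hyphal adhesin gene, had 21 counts and the list of 10 with a row took 0.00210% of counts. Of the mating type genes named after their values were seen, MTLA1 had 73 counts and MTLA2 had 8.

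Whether opaque and white transcripts exclude each other among colonies was examined over the thinned barcodes. Totals of the 2 lists correlated at 0.151, at percentile 93.8 among 10000 pairs of random lists of like expression, whose median was 0.0966. The white total was mostly ADH1, with 14586 of 17576 counts, a gene also on the glycolysis and fermentation list. No correlation without ADH1 was computed. Barcodes were then ranked by the opaque list in 1 random split of their counts and measured in the other. Of 3 equal groups of barcodes, the highest over the lowest had a WH11 ratio of 1.07 (0.856 to 1.34). The opaque list itself had a ratio of 0.979 (0.634 to 1.51) between these groups, so a difference in opaque level was not detectable at this depth. With rRNA left out, a setting chosen after seeing the data, the percentile was 60.2, and over 10 other random draws with rRNA counted it ranged from 64.0 to 95.2.

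The most abundant C. albicans transcripts outside rRNA and ribosomal proteins were ADH1 with 4373 CPM, STF2 with 4197, the glycolytic genes TDH3 with 3753 and ENO1 with 3500, and the hexose transporter gene HGT7 with 3226. Genes of the cell surface, PGA59 and PGA56, stood at 3214 and 2624. Ribosomal protein genes took 5.46% of counts, glycolysis and fermentation 2.09%, histones 0.924%, oxidative stress 0.799%, glyoxylate and beta-oxidation 0.688%, heat shock 0.486%, the TCA cycle 0.428% and amino acid biosynthesis 0.398%. Iron acquisition took 0.213% and ergosterol synthesis 0.0861%. The mating type and pheromone list took 0.00744%.

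Members of several C. albicans lists varied together over barcodes. Values with rRNA left out were added after seeing the data. The mean pair correlation of 8 histone genes was 0.213 and lay at percentile 100 among 10000 random lists of like expression (median 0.115), and at 99.01 with rRNA left out. This list holds related gene copies, such as HHF22 and HHF1, whose rows could share reads. Random lists need not hold such copies, and how far shared reads raise the percentile was not tested. Oxidative stress genes lay at percentile 99.8 and glycolytic genes at 99.8, and at 91.1 and 93.2 with rRNA left out. The white markers lay at 97.9 and 86.8, and the TCA cycle at 96.4 and 54.3. Ribosomal protein genes stood at percentile 67.8 with rRNA counted and at 100 without it. Amino acid biosynthesis lay at 96.3 and 96.6, glyoxylate and beta-oxidation at 79.4 and 17.1, heat shock at 5.45 and 9.13, and iron acquisition at 5.14 and 23.4. Of 1869 genes tested for variation, 1765 had a Fano factor (variance over mean) above 1.13, a level set from simulated barcodes with 1 common profile. The number was 3407 with no gene minimum and 256 with the A and B allele rows kept apart, the second chosen after seeing the data. Both settings tested other sets of rows than the 1869 genes. Rows kept apart also have lower means, which by itself brings Fano factors nearer 1. The fall to 256 therefore does not measure the sharing of counts. The median was 1.27 with rows summed and 1.05 with them apart. The rows of a locus shared counts: where a locus had 2 counts in a barcode, 1 fell on each row in 116816 of 156579 cases (74.6%), against 77035 (49.2%) for independent counts. The 1765 is therefore not a number of genes that varied between colonies, and C. albicans intervals are too narrow. With rows summed, RDN18 had the highest Fano factor, 181, and the highest outside rRNA were C1_08610C with 3.97, STF2 with 3.74, CR_08830W with 3.15 and ADH1 with 3.07.

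C. albicans barcodes gave 3 clusters in 1 split of the counts and 2 in the other, with an adjusted Rand index of 0.299 between them. Simulated barcodes with 1 common profile and the same depths gave 0.546, and 10 other random draws of the data gave 0.248 to 0.599. At resolution 0.25, with 2 clusters, and when clustered without ribosomal protein genes the agreement was 0.606 in each case. Median rRNA shares of the 3 clusters were 49.8%, 26.4% and 77.8%. These clusters are not described further.

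In S. cerevisiae the strain's markers were those of an a cell. The a-factor genes MFA1 and MFA2 had 12648 and 5122 counts, and MFA1 was seen in 91.5% of 1499 barcodes thinned to 1569 counts and in 95.3% of all barcodes. The alpha-factor genes MF(ALPHA)1 and MF(ALPHA)2 had 46 counts and 1 count, and STE3, the a-factor receptor gene, had 42. The alpha-specific gene SAG1 had 172 counts. STE3 was seen in 1.27% of thinned barcodes and SAG1 in 3.27%, alpha-cell genes that a cells are not known to activate, at a median of 2282 counts per barcode before thinning. BY4741 carries deletions at HIS3, LEU2, MET17 and URA3. URA3 had 3 counts and MET17 had 12, while HIS3 had 844 counts. The HIS3 deletion of this strain is internal, so a transcript end can lie outside it. Whether the HIS3 counts come from such an end was not tested. LEU2 had no row among the counts, so no value is given for it.

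The S. cerevisiae barcodes were placed in 3 clusters that differed in growth and stress transcripts. Clusters made from 1 split of the counts held 936 barcodes (46.8%, 44.6% to 49.0%), 893 barcodes (44.7%) and 170 barcodes (8.50%). Their agreement with clusters from the other split was an adjusted Rand index of 0.976, against 0.549 in simulated barcodes with 1 common profile. Barcodes simulated with 2 states were split into 4 clusters, with an agreement of 0.795 between splits. The 3 clusters are therefore not shown to be 3 states. At resolution 1 there were 6 clusters and the agreement was 0.597, and without ribosomal protein genes it was 0.602. Median counts per barcode were 2007.5, 3192 and 2002. Levels below come from the counts held out of the clustering, and each list was measured over clusters made without its own genes. Those clusters were matched to the main ones and merged, so their barcodes differ somewhat from list to list. For ribosomal proteins they held 876, 895 and 228 barcodes. Random lists of like expression had median log2 ratios over the other barcodes of -1.27 to -0.74 in cluster 1 and 0.55 to 1.19 in cluster 2, and percentiles are taken against them. Levels are scaled to totals that include ribosomal proteins, 55.5% of counts in cluster 1 and 13.8% in cluster 2. Genes outside that list therefore read higher in cluster 2 than in cluster 1 even where their part of the remaining counts is equal. Pooled over the library, ribosomal proteins took 28.6% of counts, general stress genes 4.799% and respiratory chain genes 2.15%.

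**Figure D2:**
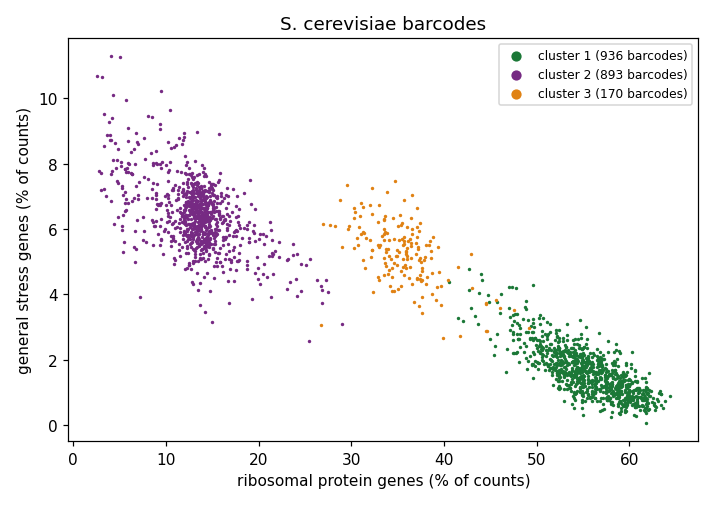
Share of counts from ribosomal protein genes (x axis, %) and from general stress genes (y axis, %) in each S. cerevisiae barcode, coloured by cluster. The median barcode held 55.5% ribosomal protein counts in cluster 1, 13.5% in cluster 2 and 35.5% in cluster 3.

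Cluster 1 was high in the transcripts of ribosomes and of their assembly. Ribosomal protein genes took 55.7% of its counts against 16.5% in the other barcodes, and 90 of 137 measured members were at least 2-fold higher, 2 at least 2-fold lower and 45 between. Of 25 ribosome biogenesis genes 9 were higher and 1 lower, with a median log2 ratio of 0.54. Their pooled ratio of 3.71 rested mostly on 1 gene, NOP10, with 4188 of 5995 counts, and was 1.70 without it (1.60 to 1.81). NOP10, part of a particle that modifies rRNA, stood at 3823 CPM in cluster 1 and 428 in cluster 2, a ratio of 8.93 (8.31 to 9.61). The genes that defined this cluster included NIP7, CGR1 and TSR2, all needed to make ribosomes, and RPL33B. All 27 general stress genes were at least 2-fold lower in cluster 1, and all 11 measured glyoxylate and gluconeogenesis genes were as well. The medians of these 2 lists lay at percentiles 0 and 0.190 among 10000 random lists of like expression.

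Cluster 2 was high in general stress, glyoxylate and gluconeogenesis, and hexose transporter transcripts. General stress genes took 6.45% of its counts against 2.18% elsewhere, with 24 of 27 members at least 2-fold higher, none 2-fold lower and 3 between. HOR7 gave 68856 of the 135159 counts, and without it the ratio was 8.14 in place of 2.96. HSP12, a stress-induced membrane protein gene, stood at 24559 CPM against 1604 in cluster 1, a ratio of 15.3 (14.6 to 16.1). TMA10 was 102-fold higher than in cluster 1 (91.0 to 114). All 11 glyoxylate and gluconeogenesis genes were at least 2-fold higher in cluster 2, including the transporter gene ADY2 at 58.3-fold over cluster 1 (19.8 to 284). Hexose transporter genes took 0.256% of counts, 10.96-fold the level elsewhere, with 5 of 8 higher and 1 lower. HXT6 and HXT7, high-affinity transporters whose near-identical sequences can share reads, were 40.3-fold and 19.5-fold higher than in cluster 1. TCA cycle genes were 3.82-fold higher in pooled counts, with 10 of 17 members higher and 1 lower, among them SDH3 at 12.4-fold over cluster 1 (9.32 to 16.9). Their median lay at percentile 81.5, inside the range of random lists, as did that of the respiratory chain genes at 52.9, with 11 of 29 members higher and 1 lower. Mitochondrially encoded genes were 24.5-fold higher, over 2 measured members, and 4.96-fold higher without OLI1 (2.78 to 9.64). Alpha-specific genes were 5.85-fold higher, with 2 of 3 members higher and none lower, and 2.26-fold higher without SAG1 (1.14 to 4.88). The mitochondrial gene OLI1, an ATP synthase subunit, stood at 2176 CPM against 74.9 in cluster 1. The stationary phase genes SPG1 and SPG4 and the respiration gene RGI2 were among those that defined the cluster. SPG4 had 21035 held-out counts there and 37 in all other barcodes. HXK1, a hexokinase gene, had 239 counts there and 0 elsewhere, at least 49.4-fold higher against a floor of 3 counts over the other barcodes.

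Cluster 3 lay between the others in ribosomal protein and general stress shares, and it shared with cluster 1 a higher level of Gcn4 targets than cluster 2. Ribosomal proteins took 38.7% of its counts over the 228 barcodes matched to it without those genes, and 35.6% over the main 170. General stress genes took 5.20%, and HOR7 gave 7870 of these 10514 counts. Without HOR7 the ratio to the other barcodes was 0.608 (0.584 to 0.632) in place of 1.09. Of 27 general stress genes 3 were at least 2-fold higher and 12 lower, with the median at percentile 0.390. Methionine and sulfur genes were 2.54-fold higher than in the other barcodes, with 9 of 18 members higher and 1 lower, and their median lay at percentile 100. In cluster 1 these genes had 4 of 18 higher and 4 lower (percentile 99.8), and in cluster 2 they had 3 higher and 6 lower (0.0600). Targets of Gcn4, a regulator of amino acid synthesis, were 2.27-fold higher in cluster 3, with 11 of 27 members higher and 1 lower, and 1.94-fold higher in cluster 1, with 11 higher and 3 lower, both at percentile 100. In cluster 2 they were lower, with 14 of 27 members lower and 3 higher, at percentile 0. LYS9, of lysine synthesis, stood at 282 CPM, against 47.5 in cluster 1 and 36.3 in cluster 2. MET14, of sulfate assimilation, stood at 457 CPM, against 198 and 56.8, and SER3, of serine synthesis, at 457 against 214 and 41.5. HOM2 at 330 CPM against 193 in cluster 1 and MET28 at 92.3 against 35.6 were also higher, by 1.71-fold (1.28 to 2.26) and 2.59-fold (1.41 to 4.59). The other named members were near cluster 1, with LEU1 at 379 CPM against 315, MET6 at 175 against 141, CYS4 at 102 against 88.6 and GCN4 at 219 against 246. The aromatic list took 0.0599% of cluster 3 counts, between 0.0492% in cluster 1 and 0.0835% in cluster 2. Its ratio to the other barcodes was 0.836, and 1.09 without ARO4 (0.877 to 1.34), with the median of the list at percentile 95.1. Ribosome biogenesis genes were lower than in clusters 1 and 2 pooled, at a ratio of 0.640, with 14 of 25 members at least 2-fold lower and none higher. They took 0.181% of cluster 3 counts, against 0.546% in cluster 1 and 0.144% in cluster 2. YRO2, YER053C-A, YLR053C, LYS9 and YKL068W-A led the defining genes of cluster 3.

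**Figure D3:**
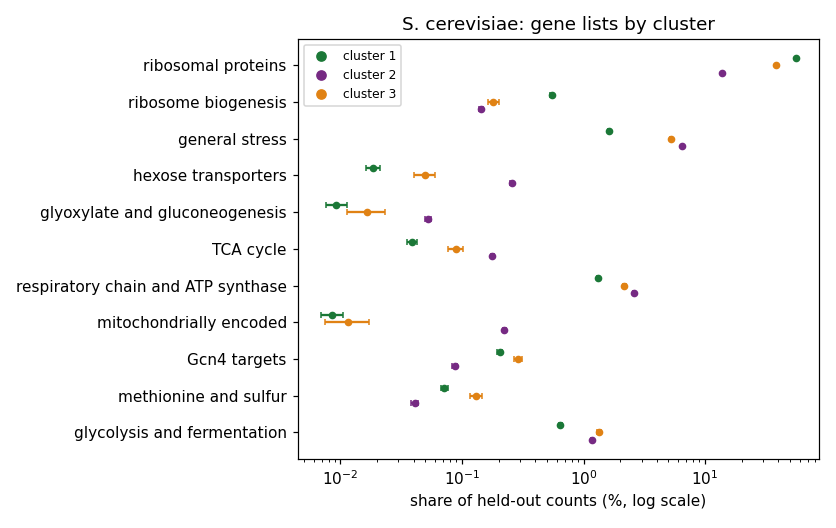
Share of held-out counts (%, log scale) of 11 gene lists in the 3 S. cerevisiae clusters, each list measured over clusters made without its own genes, with exact 95% intervals for counting error. Ribosomal proteins lie at 55.7%, 13.8% and 38.7% in clusters 1, 2 and 3, and Gcn4 targets at 0.204%, 0.0872% and 0.289%. The ribosomal protein shares are over 876, 895 and 228 barcodes.

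The remaining lists are given for cluster 2. In it, 8 of 20 glycolysis and fermentation genes were at least 2-fold higher and 4 lower, with the median at percentile 28.7. Random lists were themselves higher there, so counts of higher members are to be read with the percentile of the median. Oxidative stress genes had 12 of 18 higher and 3 lower (percentile 96.0), and heat shock genes 11 of 22 higher and none lower (52.5). Iron regulon genes had 7 of 10 higher and none lower (96.9), and phosphate regulon genes 5 of 8 higher and 1 lower (87.3). Histone genes had 2 of 10 higher and 1 lower (18.7), ergosterol synthesis genes 9 of 19 higher and 4 lower (39.0), pyrimidine synthesis genes 3 of 10 higher and 1 lower (15.6), and daughter cell separation genes 3 of 10 higher and 1 lower (23.0). The a-specific list had 2 of 7 higher and 2 lower and lay low, at percentile 2.76 in cluster 2 and 96.7 in cluster 1, with MFA2 at 393 CPM in cluster 2 and 1395 in cluster 1. Seripauperin genes had 112 counts in all.

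Genes of some of these lists varied together. Ribosomal protein, general stress and hexose transporter genes lay at percentile 100 of co-variation among 10000 random lists, glycolysis and respiratory chain genes at 99.6, and Gcn4 targets at 98.9. In lists with near-identical genes, such as HXT6 and HXT7 or paired ribosomal protein genes, shared reads could raise the percentile. This was not tested. Pyrimidine synthesis, a-specific, ergosterol synthesis and phosphate regulon genes lay at 77.9, 70.4, 59.3 and 58.5, inside the range of random lists. The respiratory chain, TCA cycle and oxidative stress lists lay at 85.3, 66.9 and 42.1 when ribosomal protein genes were left out of the depth, against 99.6, 96.1 and 93.9 with them. Under that setting pyrimidine synthesis lay at 12.2, a-specific genes at 99.7, histones at 99.6 in place of 91.7 and ribosome biogenesis at 100 in place of 84.3. Of 2205 genes tested, 690 had a Fano factor above the simulated level of 1.12, and 363 did with no gene minimum and its own simulated level. The highest were TMA10 with 24.5, HSP12 with 19.96, YNR034W-A with 16.5, 21S_rRNA with 16.3 and RPL41A with 15.9. HOR7, a stress gene, was the most abundant transcript outside the ribosomal protein list with 27030 CPM. CUP1-1 and CUP1-2, near-identical copies that can share reads, had 12257 and 12341.

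ARO4 encodes an enzyme at the entry of aromatic amino acid synthesis. In the R64 reference annotation it lies on chromosome II from 716882 to 717994 on the minus strand, with 1 coding exon and no intron (YBR249C). The build used by the authors is not given in the sources used here. ARO4 had 1832 counts, or 270 CPM (257 to 282), the highest of the 15 aromatic genes, ahead of TRP1 with 163. ARO7, ARO2 and ARO8 stood at 45.2, 37.8 and 36.9. The other members ranged from 6.33 CPM for TRP3 to 24.0 for ARO9. ARO4 was seen in 27.3% of thinned barcodes (25.04% to 29.6%) and in 41.8% of all barcodes. URA3, deleted in this strain, was seen in 0.0667% of thinned barcodes. With no colony to supply its RNA, this share does not bound ARO4 RNA passed from colony to colony. The counts do not say which ARO4 variant a colony carried.

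ARO4 and TRP1 were higher in cluster 2 than in cluster 1, by 2.72-fold (2.27 to 3.28) and 5.22-fold (3.87 to 7.21). Scaling to all counts raises such genes in cluster 2, where ribosomal proteins took 13.8% of counts against 55.5% in cluster 1. Random lists of like expression had a median log2 ratio of 0.83 for cluster 2 over the other barcodes, which is not a ratio to cluster 1 alone. ARO7 and ARO2 were lower in cluster 2 than in cluster 1, with ratios of 0.322 (0.222 to 0.464) and 0.590 (0.413 to 0.844). Over all barcodes the 15 aromatic genes had 4 higher, 3 lower and 8 between in cluster 2, with a median log2 ratio of -0.17 at percentile 1.18, and at percentile 97.8 in cluster 1. Their co-variation lay at percentile 47.1. Over 10 other random draws this percentile ranged from 4.57 to 58.4 with a mean of 14.1, so it is not fixed by these data. Barcodes with an ARO4 count in 1 split had 1.78 times the ARO4 level in the held-out split (1.32 to 2.37), and 1.09 times that of the other aromatic genes (0.852 to 1.37). Their ribosomal protein level was 0.732 times that of barcodes without one (0.725 to 0.739) and their general stress level 1.24 times. Within clusters 1, 2 and 3, as added after seeing the data, the ribosomal protein ratio was 1.01, 1.05 and 1.05, and the general stress ratio 1.01, 1.002 and 0.884. The ARO4 ratio within clusters 1 and 2 was 2.18 (1.07 to 4.12) and 1.40 (0.990 to 1.962). For the other aromatic genes the ratio within clusters 1, 2 and 3 was 0.566 (0.267 to 1.07), 0.804 (0.588 to 1.08) and 1.18 (0.357 to 3.05).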

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

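The correlations with other genes were chosen after the count was seen. The C. albicans table has a row for YFP, a fluorescent reporter that no comparison used, and it held 797 counts, where a count of 0 would allow up to 3. It was seen in 508 barcodes (25.4%, 23.5% to 27.4%) with at most 23 counts in 1 barcode. The labels used here do not say which promoter drives it. With rRNA left out and barcodes thinned to 449 counts, its Fano factor was 1.15. Over 1764 genes its correlation was highest with AOX2, an alternative oxidase gene, at 0.180, followed by C1_08610C at 0.179 and CR_08830W at 0.168. WH11 ranked 25 at 0.0719 and EFG1 ranked 1689 at -0.0466.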

How the results depend on the processing

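Chosen only after results were seen were rRNA left out, allele rows kept apart, the sharing of counts between allele rows, clustering after thinning (a setting added late, though its bound was written before its result), clusters made without each list's own genes, lists without their highest member, opaque markers against random lists, and ARO4 within clusters or under other thinnings. No paired analysis was possible because each group has 1 library and no label pairs them. Of 1043 values under alternative settings, 714 stayed within their interval, their spread over 10 random draws or 1.5 times the main count, 320 moved beyond it and 9 turned in direction. Except where stated, the cause of a change was not tested. Some of the 714 could not move. In S. cerevisiae a minimum of 500 counts kept the same barcodes, which fixed all 106 values. The median Fano factor under scaled counts and the ARO4 Fano factor under groups by ARO4 were also fixed by construction. The 714 is therefore not a measure of robustness. Without the 5% of barcodes with most counts, medians were 1204.5 and 2194 counts per barcode for C. albicans and S. cerevisiae, the white marker share 0.547%, the S. cerevisiae ribosomal protein share 32.2% and general stress share 4.43%, and ARO4 240.1 CPM. As means over barcodes these shares were 0.550%, 34.9% and 4.07%. Without a gene minimum, genes above the simulated variation numbered 3407 in C. albicans, above 1765, and 363 in S. cerevisiae, below 690. At resolution 1 both libraries gave 6 clusters, and the S. cerevisiae agreement between splits was 0.597. At resolution 0.25 agreement was 0.606 in C. albicans and 0.986 in S. cerevisiae. Clustered without ribosomal protein genes, it was 0.606 in C. albicans and 0.602 in S. cerevisiae. Between the highest and lowest of 3 equal groups of barcodes by ARO4, the held-out ARO4 ratio was 1.27. With depth taken without ribosomal protein genes, the mean pair correlation of S. cerevisiae oxidative stress genes was -0.00548.

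With rRNA left out, the C. albicans median was 602.5 counts, the opaque share 0.0357%, the white share 1.15%, and the percentile of the white and opaque correlation 60.2. Mean pair correlations became negative for the C. albicans TCA cycle (-0.000319), heat shock (-0.00476), iron acquisition (-0.00528) and glyoxylate and beta-oxidation (-0.00530) lists. In S. cerevisiae the shares became 28.9% and 4.84% and the agreement 0.987. Keeping allele rows apart by construction drops B rows from the lists and lowers the means of rows. The opaque share was then 0.00807%, the white share 0.356% and the percentile 61.2. Genes above simulated variation numbered 256, with a median Fano factor of 1.05 against 1.27. Within clusters 1, 2 and 3, the ribosomal protein ratio of barcodes with over without ARO4 was 1.01, 1.05 and 1.05, against 0.732 over all barcodes. The general stress ratio turned to 0.884 in cluster 3, and the ratio of other aromatic genes was 0.566 in cluster 1, 0.804 in cluster 2 and 1.18 in cluster 3. Depth limits the rarest markers: the opaque list rests on 546 counts.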

Other observations

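Tests chosen only after the result was seen were the gap in ribosomal protein share at like depth, the borders of clusters made without ribosomal protein genes, the mixing of colonies, the barcode bases, the random-list controls for opaque markers, the allele rows, the chromosome ends and the repeats for ARO4 in cluster 1.

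Within cluster 1 of S. cerevisiae, ARO4 varied more over thinned barcodes than each of the 200 genes of like mean, with a Fano factor of 1.61 and at most 8 counts in a barcode. In clusters 2 and 3 it lay at percentiles 69 and 27. Over 10 random thinnings the Fano factor in cluster 1 ranged from 1.27 to 1.72. Without the barcode highest in ARO4 it ranged from 1.10 to 1.40 (percentile 95.5 to 100), and without the highest 5 its median was 0.999 (median percentile 89.2, range 23.5 to 98.5). Leaving out a gene's highest barcodes lowers its Fano factor by construction, so these values do not decide what the excess rests on.

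The 3 clusters of S. cerevisiae barcodes were the plainest pattern. A bound of 0.8 on the adjusted Rand index, set beforehand, was not reached either after thinning to 1 depth (0.774) or without ribosomal protein genes (0.727), where in both cases 4 clusters were found, so neither test decided. Other values cover narrower questions. At like depth the gap in ribosomal protein share between clusters 1 and 2 was 43.1 percentage points, against 41.8 over all barcodes, which argues against depth for that gap. Of all barcodes, 96.7% lay in a cluster, made without those genes, that was mostly of their own main cluster. Splitting a cluster further cannot lower that share, so neither value decides that there are 3 groups. Cluster 3 as barcodes holding colonies of both other kinds would need genes 10-fold higher in cluster 2 at 0.477 of the way from cluster 1 to 2, and their median over 292 genes was 0.114 (quartiles 0.0308 and 0.240). Separate bead lots or runs stay a candidate explanation. At like depth the share of C among barcode bases was higher in cluster 1 than in cluster 2 by 2.35 percentage points (0.258 to 4.44, normal approximation). C was the only base compared between clusters, in a test chosen after seeing the data, so this is weak evidence. A difference in growth state or in ARO4 variant between colonies was not tested.

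For the white markers in the library labelled opaque, a minority of opaque colonies could be present. Barcodes with 2 or more counts of opaque markers numbered 109, above the 94.0 that bounded libraries simulated with 1 common profile, which met the bound set beforehand. That bound did not discriminate, since 99.91% of 10000 random lists of like expression passed it too, and the opaque list lay at percentile 14.0 among them, with at most 8 counts in a barcode. For OP4, SAP1, SAP3, CDR3, PBR1 and WOR1 alone, 8 barcodes had 2 or more counts and none had over 2, above the simulated bound of 6 and at percentile 7.34 among such random lists. In 72 of 76 cases where an opaque locus had 2 counts in a barcode, 1 fell on each allele row, so such pairs are not independent and a minority cannot be told apart from this, while a mislabelled sample or colonies that had switched to white were not tested.

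Some C. albicans genes took a larger part of the non-rRNA counts where the rRNA share was high. ITS2, a spacer of the rRNA genes, led with a Spearman correlation of 0.370, followed by NPL3 at 0.327, C3_00030C at 0.296 and C3_00010C at 0.248. Of the 20 leading genes, 45% lay within 20 loci of a chromosome end (23.1% to 68.5%), against 8.05% of 1776 genes, so a property of chromosome ends is a candidate explanation. Fewer messenger counts in such barcodes would weaken the correlation after thinning, yet its median became 1.10 times that before. No biological explanation was tested.

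Of 2000 C. albicans barcodes, 334 had a neighbour that differed by 1 base, against 219 to 317 in 100 random draws with the same bases per position. In S. cerevisiae 116 did, against 82 to 143. The median profile correlation of the 198 C. albicans pairs was 0.00991, against -0.00117 over all barcodes. For the 60 S. cerevisiae pairs it was 0.101, against 0.0127.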
